A study of Mus musculus with 4 samples.

How the data were processed

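RNA was sequenced from 2 groups of mouse samples, with 2 libraries in each. Adipose-derived regenerative cells (ADRCs) are the plastic-adherent stromal cells obtained by collagenase digestion of fat. Per the labels, they came from the inguinal and axillary white fat of C57BL/6J mice aged 8 weeks and were at passage 2. The other group was labelled as whole heart of mouse embryos at embryonic day 11.5 (E11.5). Per the labels' protocols, total RNA was purified on columns, treated with DNase, selected for poly(A) tails and made into libraries with a kit that is not stated to keep the strand, so reads of a gene and of an overlapping antisense gene cannot be told apart.

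The authors deposited 1 gene table for all 4 libraries. Per the submitters' processing notes the genome build was GRCm38; the aligner, its version and the rule for reads with several matches are not given in the sources used here. Per the file headers, the deposited counts are reads per gene, split into exon and intron reads and given in total (reads with several matches included) or for uniquely mapped reads. The deposited RPKM values equalled total exon reads scaled to exon length and to 1 constant per library in 100.0% of the rows with reads, within a relative tolerance of 1e-06. The constant was derived from the RPKM values themselves and was not checked against a count of mapped reads. The deposited signal column named normalized expression by the file headers had the same sum in every library, 374604.3. Quantile normalization of RPKM gives equal sums, but so does scaling to a common total, and these were not told apart. Per the file headers the authors also deposited p-values and FDR values of an EDGE test, a t-test and Baggerley's test, and a signed score of fold change, positive where the heart was higher. Which values the EDGE test was run on is not given in the sources used here. Exon length, chromosome, start and end are other columns of the deposited table.

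The table had 50600 rows, of which 99.56% carried a gene identifier present in the GRCm38 annotation used for comparison (GENCODE M21). Of these, 94.84% had the same start once the deposited start, which counts from 0, was raised by 1, and coordinates are printed counting from 1. In 18045 rows the exon length was 0 and no exon read was counted, and 28651 rows had no exon read in any library. Columns were matched to samples by group and replicate number in their names. The names of the ADRC columns contain P1, whereas the labels say passage 2, and the second one begins with iADRC. The names of the heart columns begin with E11.5_CM, whereas the labels say whole heart, and CM is not spelled out. The column names also place both ADRC libraries in 1 sequencing lane and both heart libraries in another, so lane and group cannot be told apart. A further 32 columns of values per library were not used.

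Total exon reads were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by the trimmed mean of M values (TMM; factors 0.968, 0.988, 1.004 and 1.041), and the quasi-likelihood F test compared heart with ADRC. p-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. CPM values are exon reads scaled to the TMM-adjusted library size, with mean ± SD over the 2 libraries of a group, and standard errors (SE) of log2 fold changes were taken from the F statistic. The 28 gene lists, the tests and the rule for named genes were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and adjusted over 27 lists, the sex-linked list being given as values only. Camera with an estimated correlation and fry were the alternatives. With an estimated correlation, camera refers its statistic to the 2 residual degrees of freedom, so small p-values are hard to reach.

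The rule named all 6 factors of the study, the 2 members with the largest absolute log2 fold change from each other main list, the most abundant tested member of each further list, and the 3 largest changes in each direction outside the lists. Main-list and outside genes had to pass the threshold with a mean of at least 10 CPM in a group, and gene models without a proper name were left out. Where a group had 0 reads in both libraries, the fold is a lower bound against a floor of 3 reads over the group. With 1 to 3 reads, the ratio is given with a 95% Poisson interval of the smaller count. The same interval is given for named genes with 4 to 24 reads in a group. Intervals and floors cover counting error only.

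The alternatives planned for the counts were DESeq2 size factors, library totals and upper-quartile scaling in the same test, the DESeq2 1.42.0 Wald test, limma-voom, no filter (at least 1 read), at least 50 reads in 2 libraries, leaving out each library, a replicate block, a test against a 2-fold change, and leaving out haemoglobin and mitochondrially encoded genes. Uniquely mapped reads and libraries thinned to the smallest total were added after the data had been seen. The alternatives planned for a table of normalized values only were not run because the table holds counts.

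The tests were tested on simulated data for this comparison with 200 changed genes among 15562. edgeR recovered 31.3% of 1.5-fold, 77.6% of 2-fold and 95.5% of 4-fold changes, and called 0.06% of the unchanged genes. In the data itself 11674 of 15562 genes were called, so these rates need not hold there. In a simulated list of 20 raised genes, camera with an estimated correlation gave p = 0.00126. Its genes were drawn independently against a mostly unchanged background, so it does not show that this test could pass lists here. Depth ranged from 34133068 to 99784339 exon reads. The labels do not say whether replicates came from separate animals or cultures, so the spread behind the p-values may be technical. That spread was mostly shared across genes, with 28.9 prior against 2 residual degrees of freedom. A gene's p-value and SE therefore reflect its own spread between replicates only weakly. For genes with few reads in a group, the SE should be read beside the counting interval. Other tools were Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.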

Results

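Poly(A)-selected RNA was sequenced from cultured ADRCs of adult mouse fat and from tissue labelled as whole E11.5 mouse heart, with 2 libraries per group. The ADRC libraries held 34133068 and 47300963 exon reads and the heart libraries 37509173 and 99784339. Mitochondrially encoded genes took 1.56% and 1.61% of exon reads in the ADRC libraries and 6.17% and 7.70% in the heart libraries. The comparison asks which genes distinguish embryonic heart from the fat-derived cells that the study set out to turn toward cardiomyocytes.

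Replicates lay far closer to each other than the groups did. Across 15562 genes, Pearson's r of log2(CPM + 1) was 0.994 between the ADRC libraries and 0.996 between the heart libraries, against 0.767 to 0.770 between groups. These correlations are across genes, which are not independent replicates. The median absolute log2 difference was 0.151 between ADRC replicates, 0.129 between heart replicates and 0.704 between the group means. Replicate counts differed by more than sampling noise, with a chi-square per degree of freedom of 40 in ADRCs and 44.4 in hearts.

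Most genes differed between heart and ADRCs. Most contractile, calcium-handling and fatty acid or creatine energy genes were higher in heart. Most matrix, Hox, and senescence or inflammation genes were higher in ADRCs. Of 27 lists tested with camera, 21 passed at the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.12). The second count rests on 2 residual degrees of freedom and does not show that correlated genes undo the calls. For the 6 factors the estimated correlation was -0.04, under the preset 0.01, yet the camera adjusted p rose from 3.6e-07 to 0.12. Their list is not independent evidence, since the study may have chosen the factors on these samples. Among the lists that passed, estimates ranged from -0.09 (further reprogramming factors) to 0.84 (erythroid genes). They were 0.51 for respiratory chain genes and 0.16 for cell cycle genes. In lists above the preset, correlation may also have raised the p-values, which was not separated from the degrees of freedom. By edgeR's quasi-likelihood test, 6026 genes were higher and 5648 lower in heart among 15562 tested at an adjusted p under 0.05. Of these, 4112 were at least 2-fold higher and 3492 at least 2-fold lower. A test against a minimum change of 2-fold called 3284 higher and 2797 lower. Because both libraries of a group shared a lane in the column names, lane and group cannot be told apart in any of these counts.

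All 6 factors that the study went on to express in ADRCs were higher in heart. Gata4, a zinc-finger factor of heart muscle formation, was at 0.242 ± 0.172 CPM in ADRCs and 163.8 ± 2.80 CPM in heart (SD, n = 2), a log2 fold change of 9.28 (SE 0.267), or 10.37 without ADRC replicate 2. Myocd, the serum response factor coactivator myocardin, rose by 5.73 on the log2 scale (SE 0.258), from 0.839 ± 0.630 to 47.5 ± 3.61 CPM. Its ADRC libraries were at 0.394 and 1.28 CPM, and without ADRC replicate 2 the log2 fold change was 6.90. Klf15 reached 30.9 ± 1.9 CPM in heart against 3.90 ± 0.911 in ADRCs, a log2 fold change of 3.00 (SE 0.189). ADRCs already held Gata6 at 18.4 ± 0.636 CPM, Mef2a at 43.3 ± 5.90 CPM and Smarcd3, which encodes the chromatin remodelling subunit Baf60c, at 19.7 ± 3.11 CPM. Their log2 fold changes were 2.99 (SE 0.161), 2.49 (SE 0.166) and 2.10 (SE 0.164). The largest edgeR adjusted p among the 6 was 5.37e-13, for Smarcd3. All 6 also passed when adjusted over the list alone, which is not independent evidence because the study may have chosen the factors on these samples. The list had a camera adjusted p of 3.6e-07, and an adjusted p = 0.12 with an estimated correlation. For the same reason, these set tests are not independent evidence either.

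**Figure D1:**
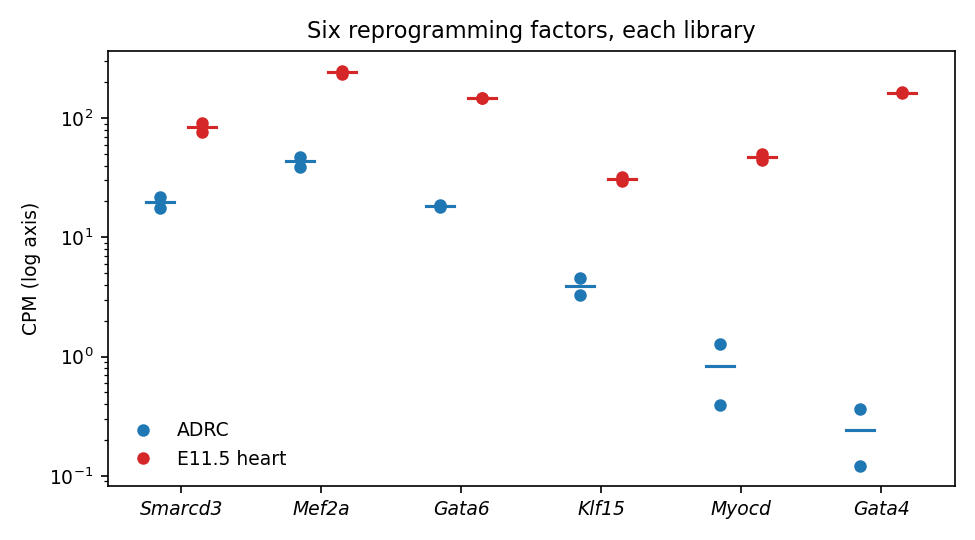
CPM on a log axis of the 6 factors in each library; points are libraries (blue ADRC, red E11.5 heart; 2 per group) and bars are group means. Gata4 and Myocd were under 2 CPM in both ADRC libraries, while Smarcd3, Gata6 and Mef2a were above 15 CPM there.

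On GRCm38 the annotated genes lie at chromosome 14, 63198922 to 63271692 (Gata4, minus strand), chromosome 11, 65176561 to 65269989 (Myocd, minus strand) and chromosome 6, 90462576 to 90475238 (Klf15, plus strand). Gata6 lies at chromosome 18, 11052510 to 11085635 (plus strand), Mef2a at chromosome 7, 67231163 to 67372858 (minus strand) and Smarcd3 at chromosome 5, 24590818 to 24624411 (minus strand). Their identifiers in the table are ENSMUSG00000021944, ENSMUSG00000020542, ENSMUSG00000030087, ENSMUSG00000005836, ENSMUSG00000030557 and ENSMUSG00000028949 in the same order. The values are exon reads, which the table assigns to whole genes and not to transcripts.

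Among other heart transcription factors, more rose than fell in heart. All 8 tested members of a list of further reprogramming factors rose, with a median log2 fold change of 4.34 (camera adjusted p 5.5e-09; adjusted p = 0.12 with an estimated correlation). Tbx20, a T-box factor of the developing heart, was at 178.9 ± 6.78 CPM in heart and 0.0535 ± 0.0757 CPM in ADRCs, where replicate 1 had 0 reads. ADRC replicate 2 had 5 reads, and the ratio was 2890-fold (95% counting interval 1240 to 8900). Nkx2-5, a homeobox factor of heart progenitors and muscle, was at 86.2 ± 18.3 CPM in heart, with 3 reads in both ADRC libraries together, a 2130-fold ratio (95% counting interval 729 to 10300). With so few ADRC reads, the fitted log2 fold changes moved from 11.43 to 10.70 and 16.34 for Tbx20 and from 11.07 to 11.85 and 10.41 for Nkx2-5 without ADRC replicates 1 and 2. In the broader list of cardiac transcription factors, 14 of 23 rose, 6 fell and 3 did not pass (camera adjusted p 7.4e-04; adjusted p = 0.24 with an estimated correlation). Irx4, an Iroquois factor of the ventricle, was at least 2280-fold higher, and Smyd1, a muscle methyltransferase, reached 516.7 ± 31.6 CPM against 0.119 ± 0.0465 CPM. Smyd1 had 5 and 4 ADRC reads, a 4490-fold ratio (95% counting interval 2360 to 9810). When p-values were adjusted over the list alone, 8 of 8 reprogramming factors rose, and 14 cardiac factors rose while 7 fell.

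Genes of the contractile apparatus showed the largest list median. Of 28 sarcomere genes 27 rose and none fell, with a median log2 fold change of 12.08 (camera adjusted p 3.6e-64; adjusted p = 0.12 with an estimated correlation). Myh7, the slow beta myosin heavy chain, was at 24010 ± 4374 CPM in heart and 1.5 ± 0.275 in ADRCs, and Mybpc3, cardiac myosin-binding protein C, at 4171 ± 538.6 against 0.206 ± 0.163. The fitted log2 fold change of Mybpc3 was 14.17, or 15.45 without ADRC replicate 2. Mybpc3 had 3 and 15 ADRC reads, a 17700-fold ratio (95% counting interval 11200 to 29900). Of 29 calcium-handling and ion channel genes 27 rose and 1 fell, or 0 with the filter of 50 reads (median 6.38, camera adjusted p 4.1e-30; adjusted p = 0.12 with an estimated correlation). Ryr2, the calcium release channel of the sarcoplasmic reticulum, was at 551.2 ± 19.7 CPM in heart, with 1 and 4 reads in the ADRC libraries. Its ratio was 8690-fold with a 95% counting interval of 3720 to 26800, and the fitted log2 fold change of 13.05 became 14.05 without ADRC replicate 2. Pln, the inhibitor phospholamban, rose by 13.09 on the log2 scale (SE 0.324; 13.79 without ADRC replicate 2), but 50.2% of its reads were unique, so its level is uncertain. Pln had 5 and 15 ADRC reads, a 9170-fold ratio (95% counting interval 5940 to 15000). Among 23 heart signalling genes 13 rose and 7 fell (camera adjusted p 0.0084; adjusted p = 0.28 with an estimated correlation). Bmp10, a growth factor of trabecular muscle, was at least 1550-fold higher and Erbb4, a neuregulin receptor, at least 422-fold higher. With p-values adjusted over the list alone, rising and falling members were 27 and 0, 27 and 1, and 13 and 7 in these lists.

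**Figure D2:**
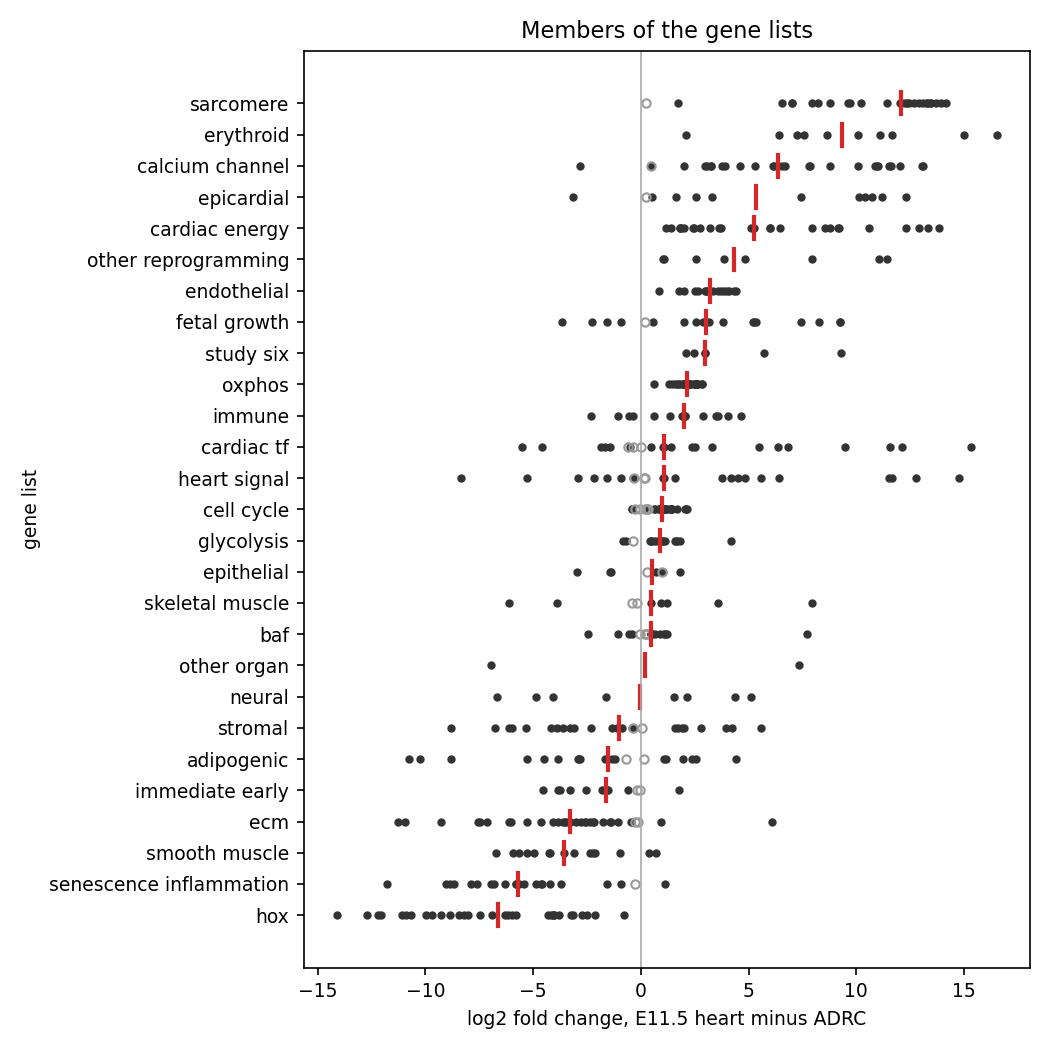
Log2 fold changes, heart minus ADRC, of the tested members of 27 gene lists, ordered by median; filled points passed an adjusted p of 0.05, open points did not, and red bars are medians. The sarcomere list has the highest median, 12.08, and the Hox list the lowest, -6.61 (-5.99 with genes of 3 reads or fewer in a group at their bound); fitted values of such genes depend on the prior count.

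Most matrix genes were higher in ADRCs, while stromal and adipogenic genes went both ways. Of 33 extracellular matrix genes 29 fell in heart and 2 rose, with a median log2 fold change of -3.28 (camera adjusted p 1.6e-20; adjusted p = 0.12 with an estimated correlation). S100a4, a calcium-binding protein of fibroblasts, was at 2703 ± 327.2 CPM in ADRCs and 1.41 ± 0.301 in heart, with 59.8% of its reads unique. Mmp3, a matrix metalloprotease, was at 57.6 ± 17.7 CPM in ADRCs, with 3 reads in heart, a 2620-fold ratio (95% counting interval 896 to 12700). Its fitted log2 fold change of -11.25 became -12.23 and -9.99 without E11.5 heart replicates 1 and 2. Among 26 stromal genes 16 fell and 8 rose (camera adjusted p 6.6e-04; adjusted p = 0.14 with an estimated correlation). Tbx15, a T-box factor of fat and limb, fell by 8.79 on the log2 scale (SE 0.250), and Ly6a, which encodes the stem cell antigen Sca-1, fell by 6.78 (SE 0.239). Of 20 adipogenic genes 12 fell and 6 rose (camera adjusted p 0.0084; adjusted p = 0.22 with an estimated correlation). Adipoq, the fat hormone adiponectin, was at 10.6 ± 2.70 CPM in ADRCs and Cfd, adipsin, at 20.2 ± 12.4 CPM. Their ratios to heart were 485-fold (interval 166 to 2350) and 1320-fold (interval 365 to 10900). The fitted log2 fold change of Adipoq, -8.80, became -9.79 and -7.55 without E11.5 heart replicates 1 and 2, and that of Cfd, -10.25, became -9.44 without ADRC replicate 1 and -9.39 without E11.5 heart replicate 2. Falling and rising members adjusted over the list alone were 29 and 2, 17 and 8, and 12 and 6.

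Most smooth muscle, early-response, and senescence or inflammation genes were also higher in ADRCs. Of 15 smooth muscle genes 13 fell in heart and 2 rose, or 1 without ADRC replicate 1 or E11.5 heart replicate 1 (median -3.55, camera adjusted p 1.0e-11; adjusted p = 0.12 with an estimated correlation), and Acta2, smooth muscle actin, was at 6710 ± 191 CPM in ADRCs and 1564 ± 233.7 in heart. Of 22 senescence and inflammation genes 20 fell and 1 rose (median -5.72, camera adjusted p 4.2e-20; adjusted p = 0.14 with an estimated correlation). Csf1, a macrophage growth factor, was at 2553 ± 203.7 CPM in ADRCs and 10.7 ± 0.720 in heart. Macrophage transcripts were low beside it in ADRCs, Lyz2 at 63.4 ± 3.47 CPM and C1qb at 1.5 ± 0.275 CPM. Of 14 immediate early genes 11 fell and 1 rose (camera adjusted p 7.5e-05; adjusted p = 0.24 with an estimated correlation), while Jun, the most abundant, was at 85.5 ± 4.06 and 82.3 ± 5.49 CPM (edgeR adjusted p 0.746). The same counts adjusted over the list alone were 13 and 2, 20 and 1, and 11 and 1.

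Most energy genes were higher in heart. All 27 tested genes of cardiac energy supply rose, with a median log2 fold change of 5.25 (camera adjusted p 4.8e-33; adjusted p = 0.12 with an estimated correlation), and Ckm, muscle creatine kinase, was at 4396 ± 842.9 CPM against 0.283 ± 0.144, a log2 fold change of 13.84 that was 14.54 without ADRC replicate 2. All 32 nuclear genes of the respiratory chain rose (median 2.14, camera adjusted p 7.8e-12; adjusted p = 0.28 with an estimated correlation), alongside the higher mitochondrial share of reads. Atp5b, a subunit of ATP synthase, was at 5047 ± 100.6 CPM against 1174 ± 88.3. Of 16 glycolysis genes 13 rose and 2 fell (camera adjusted p 0.029; adjusted p = 0.47 with an estimated correlation). That call was lost without ADRC replicate 2 (adjusted p 0.059). Pkm, pyruvate kinase, was at 2800 ± 269.6 CPM in heart and 3607 ± 287.2 in ADRCs (edgeR adjusted p 0.0622), and passed the threshold with all 4 libraries by DESeq2 (0.021), limma-voom (0.047) and the replicate block (0.011), and without ADRC replicate 2 (0.013). Rising and falling members adjusted over the list alone were 27 and 0, 32 and 0, and 13 and 3.

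Proliferation and fetal growth genes rose more often than they fell. Of 31 cell cycle genes 24 were higher in heart and 2 lower (median 0.98, camera adjusted p 0.0024; adjusted p = 0.37 with an estimated correlation); the lower count was 0 without E11.5 heart replicate 2 and 1 without replicate 1 of either group. Top2a, the topoisomerase of dividing cells, was at 282.6 ± 2.89 CPM in heart and 105.9 ± 3.47 in ADRCs. Of 18 fetal growth genes 13 rose and 4 fell (median 3.03, camera adjusted p 3.3e-07; adjusted p = 0.12 with an estimated correlation), and H19, an imprinted noncoding RNA, was at 6773 ± 921.7 CPM against 22.0 ± 8.01. Among 17 genes of BAF chromatin remodelling, 9 rose and 4 fell, and the list did not pass (camera adjusted p 0.37). Smarca4, its ATPase Brg1, fell by 0.40 on the log2 scale (SE 0.157, edgeR adjusted p 0.0232), a call lost with upper-quartile scaling (0.053), against a 2-fold change, without ADRC replicate 2 (0.072) and without E11.5 heart replicates 1 (0.060) or 2 (0.27). Adjusted over the list alone, rising and falling members were 25 and 2, 13 and 4, and 9 and 4.

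Red blood cell genes were higher in heart. All 10 tested erythroid genes rose, also when adjusted over the list alone (median log2 fold change 9.36, or 8.69 with genes of 3 reads or fewer at their bound; camera adjusted p 9.6e-10; adjusted p = 0.24 with an estimated correlation). Hbb-bs, an adult beta globin, was at 1720 ± 504 CPM in heart and 0.0428 ± 0.0605 in ADRCs, with 46.0% of its reads unique, so its split from other adult globins is uncertain. It had 0 and 4 reads in the ADRC libraries, and its fitted log2 fold change of 15 was 14.27 and 19.61 without ADRC replicates 1 and 2. The embryonic globins Hbb-y, Hba-x and Hbb-bh1 were at 0.922 ± 0.160, 0.476 ± 0.265 and 0.0554 ± 0.0033 CPM in heart, with 0 reads in ADRCs. They made up 0.0322% of globin reads in the pooled heart libraries, which bears on the labelled stage and is taken up under Other observations.

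**Figure D3:**
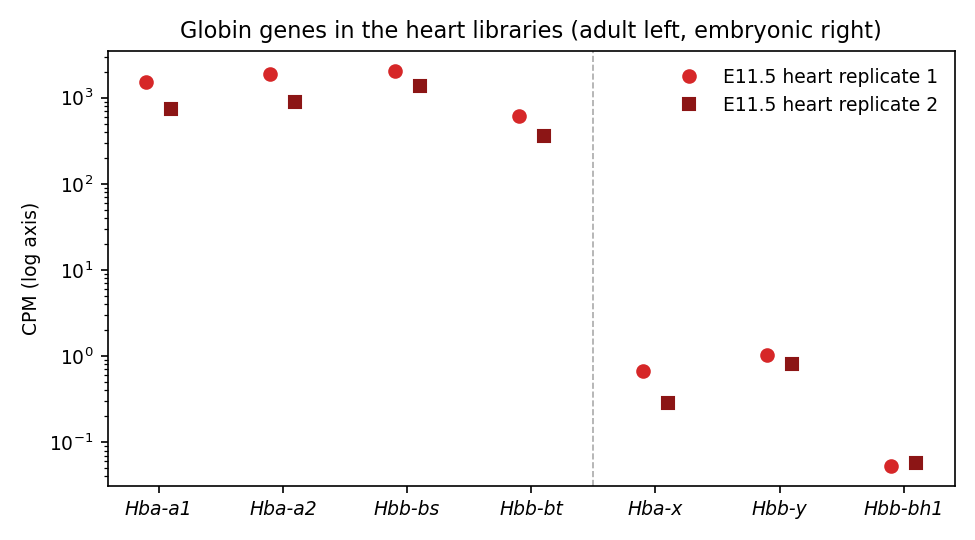
CPM on a log axis of 4 adult (left) and 3 embryonic (right) globin genes in the 2 E11.5 heart libraries, 1 point per library. Adult globins lie between 357 and 2070 CPM and embryonic globins between 0.0531 and 1.04 CPM.

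Outside the lists, genes were ranked by fitted log2 fold change among those past the threshold with at least 10 CPM in a group. Where a group had 0 reads, that rank depends on the prior count. The largest rises belonged to Trim63, a muscle ubiquitin ligase, Ptgds, a prostaglandin D synthase, and Kcnj11, a subunit of ATP-sensitive potassium channels. They were at 239.4 ± 20.5, 159.0 ± 11.4 and 61.4 ± 2.50 CPM in heart with 0 reads in ADRCs, at least 6190-fold, 4330-fold and 1610-fold higher. The largest falls belonged to Grem1, an antagonist of bone morphogenetic proteins, Emx2, a homeobox factor, and Akr1c18, a steroid dehydrogenase. Emx2 and Akr1c18 had 0 reads in heart and were at least 1800-fold and 1040-fold lower. Grem1 was at 132.4 ± 37.5 CPM in ADRCs and had 1 read in heart, a 19400-fold ratio (interval 3480 to 765000). Its fitted log2 fold change of -13.80 was -15.34 without E11.5 heart replicate 2, which held that read.

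In the authors' deposited table, the EDGE test gave 2586 genes with an FDR under 0.05, of which 1189 were higher and 1397 lower in heart. All 2586 were also called by edgeR here, in the same direction, but edgeR called 11674 of the 15562 tested genes. The authors' deposited table lists signed fold changes of 222 for Gata4, 29.4 for Myocd, 8.01 for Gata6, 7.54 for Klf15, 5.61 for Mef2a and 4.27 for Smarcd3. The folds fitted by edgeR were larger for Gata4 (622) and Myocd (53.1). They were 7.96, 8.01, 5.61 and 4.28 for the others in the same order.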

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

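Reads outside the exon counts used above stood in columns and rows that no comparison used, and are given as values. Reads in introns made up 2.23% and 2.72% of gene reads in the ADRC libraries and 3.07% and 3.6% in the heart libraries. Gene reads on rows with an exon length of 0, which hold no exon reads by construction, numbered 32372 and 44747 in the ADRC libraries and 79196 and 292682 in the heart libraries. They were 0.0927% and 0.092% of gene reads in ADRCs and 0.205% and 0.283% in hearts. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 together held 48.4% and 49.0% of them in ADRCs and 74.5% and 80.5% in hearts. No explanation was tested for these values.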

How the results depend on the processing

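The total of 11674 differing genes stayed within a factor of 1.5 under every alternative except the test against a 2-fold change, which called 6081 genes (3284 higher and 2797 lower in heart) because its null hypothesis is wider. Leaving out 1 library gave 10206 to 11420 genes, the lone library of the reduced group being assumed to vary like the other group. In those fits, in the replicate block and without a filter, edgeR gave every gene the spread of its trend (an infinite prior, against 28.9 prior degrees of freedom with all libraries), so they test the stability of calls weakly. The replicate block gave 11948 genes; replicate numbers are not said to pair libraries, and the differences between replicates 1 and 2 correlated at 0.10 between groups across 15562 genes. Of the list calls, 21 passed camera with a preset correlation and 0 with an estimated correlation. In the latter the lowest adjusted p was 0.12, on 2 residual degrees of freedom. The fry test, which tests a list against no change and not against other genes, called 22 lists, the BAF list (adjusted p 0.016) among them. Among the alternatives other than the estimated correlation, the glycolysis call was lost without ADRC replicate 2, and the immune list (adjusted p 0.069) passed under 6 of them. Leaving out 1 library moved the fitted fold of 15 named genes by over 1.5 times, and none of these lost its call. No named gene that passed the threshold with all libraries reversed in any alternative, and reversal was not assessed for those that did not pass. Smarca4, Lyz2, Acta1 and Pkm changed sides of the threshold in at least 1 alternative, and the cause was not tested. With a pseudocount of 0.1, r between groups was 0.736 to 0.741, and the median log2 differences were 0.199 between ADRC replicates, 0.163 between heart replicates and 0.939 between group means. Without a filter, r was 0.997 between ADRC replicates and 0.863 to 0.866 between groups, and these differences were 0.097, 0.086 and 0.385; the filter removes low genes, whose log values lie near 0. Replicate agreement was not computed with a library left out, since the reduced group then has no replicate pair. The uniquely mapped and thinned alternatives were chosen after seeing the data and gave 11710 and 11380 genes.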

Other observations

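Lists not described above covered position, other cell types and sex. All 32 tested Hox genes, which mark position along the body, were lower in heart (median log2 fold change -6.61, or -5.99 with genes of 3 reads or fewer at their bound; camera adjusted p 7.2e-16; adjusted p = 0.24 with an estimated correlation). Hoxc6 was at 42.8 ± 1.29 CPM in ADRCs and 0.0422 ± 0.0221 in heart, a log2 fold change of -9.70 that was -10.48 without E11.5 heart replicate 2. All 16 endothelial genes rose in heart (median 3.22, camera adjusted p 3.2e-11; adjusted p = 0.13 with an estimated correlation), and Cdh5, the cadherin of vessel lining, was at 199.6 ± 8.47 CPM against 23.7 ± 10.9 in ADRCs. Of 12 epicardial genes 10 rose and 1 fell (median 5.36, or 4.83 at the bounds; camera adjusted p 1.5e-04; adjusted p = 0.24 with an estimated correlation). The exception was Krt19, a keratin of epithelia, at 113.0 ± 9.47 CPM in ADRCs and 12.8 ± 0.991 in heart. The counts adjusted over the list alone were the same in these lists.

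The remaining lists did not pass at the preset correlation with all libraries. Of 14 immune genes 10 rose and 4 fell in heart (camera adjusted p 0.069). That list passed without a filter (0.03), with the replicate block (0.046), without E11.5 heart replicate 1 (0.023), without ADRC replicate 2 (0.049), with uniquely mapped reads (0.041) and with thinned libraries (0.046); with an estimated correlation its adjusted p = 0.68. The falling count was 2 without E11.5 heart replicate 1 and also with library totals, upper-quartile scaling, DESeq2, limma-voom or the filter of 50 reads. Lyz2, macrophage lysozyme, was lower in heart by 1.06 on the log2 scale. The neural list had 4 rising (2 with the filter of 50 reads) and 4 falling members (camera adjusted p 0.27), and Tubb3, a neuronal tubulin, was at 144.8 ± 18.0 CPM in ADRCs and 1.47 ± 0.220 in heart. Of 9 skeletal muscle genes 5 rose and 2 fell, or 1 with that filter (camera adjusted p 0.74); Acta1, skeletal actin, was at 74.5 ± 13.6 CPM in heart and 52.9 ± 5.78 in ADRCs, a call lost without E11.5 heart replicate 1. Of 8 epithelial genes 3 rose and 3 fell, or 0 with that filter (camera adjusted p 0.98), and Krt18 was at 7.06 ± 0.226 CPM in heart and 2.01 ± 0.277 in ADRCs. The other-organ list had 2 tested members, of which 1 rose and 1 fell, or 0 and 0 with that filter (camera adjusted p 0.74, its direction and median differing in sign); Sox2 was at 1.94 ± 1.25 CPM in ADRCs with 2 reads in heart, and its fitted log2 fold change of -6.93 was -6.05 without ADRC replicate 2 and -9.27 without E11.5 heart replicate 2. Counts adjusted over the list alone were the same except that 4 epithelial genes rose. Xist had 1 and 3 reads in the ADRC libraries and 2 and 6 in the heart libraries, while the Y-linked gene Eif2s3y was at 57.3, 49.2, 52.6 and 68.3 CPM.

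Of the tests below, those on embryonic globins, troponin levels, lanes, immune transcripts and immediate early genes were chosen after the values were seen. In the heart libraries the adult globins were abundant, Hbb-bs at 1720 ± 504 CPM, while the embryonic globins Hbb-y and Hba-x were at 0.922 ± 0.160 and 0.476 ± 0.265 CPM. Embryonic globins made up 0.0287% (95% Wilson interval 0.0226 to 0.0365) and 0.0345% (0.0288 to 0.0412) of globin reads in the 2 libraries. Reads shared between paralogs do not account for this, since embryonic globins were 0.0862% of uniquely mapped globin reads, and primitive red cells, which carry embryonic globins at this stage, are argued against as the main source by the pooled share of 0.0322%. Other values that bear on stage or blood in heart were Isl1 at 0.163 CPM, Myl7 at 266 and Myl2 at 11000, Sln at 4.55, S100a8 at 2.86 and S100a9 at 4.73, with Tnni1, the fetal troponin I, at 1.83 times Tnni3. A candidate explanation is tissue older than the label says, or blood of an older animal, but no heart of another stage was analysed here, so these cannot be told apart.

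The respiratory chain genes rose together in heart by a median of 2.14 on the log2 scale (quartiles 1.97 and 2.53). Without haemoglobin and mitochondrially encoded genes the median was again 2.14, and their share of the library totals can move a log2 ratio by at most 0.10. Gene length is argued against as well, since 589 genes outside the lists of like exon length had a median of -0.05 (quartiles -0.97 and 1.23). The lanes named in the columns held libraries of both groups in 0 of 2 cases, so a lane effect cannot be told apart from the group, and the difference between tissues stays open and untested.

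Most genes of the senescence and inflammation list were higher in ADRCs, with Csf1 the most abundant of the list over the 4 libraries. The immune list summed to 109 CPM in ADRCs, 2.05% of the 5330 CPM of the senescence and inflammation list. Csf1 alone was at 2553 CPM and Lyz2 at 63.4 CPM there, so single genes weigh heavily in both sums. Macrophages in the cultures are an unlikely source of most of the summed signal, although Lyz2 leaves room for a small share. The sums do not measure the source of each gene. Stress during harvest may contribute, as 11 of 14 immediate early genes were higher in ADRCs, but culture differs between the groups too and cannot be told apart from it.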
